A study of Bos taurus with 12 samples.

How the data were processed

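The data were 12 libraries of bovine oocytes, 3 input and 3 immunoprecipitated libraries from each of the GV and MII stages, grouped by the titles in the labels. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, fragmented and incubated with an antibody against m6A, and libraries were made with uracil-marked second strands, which keeps the strand, and sequenced in pairs. Poly(A) selection means that abundance here is that of RNA the beads bound, so a change of tail length can enter it. Per the submitters' processing notes, fastp 0.19.4, HISAT2 2.0.4, StringTie 2.1.2, edgeR 4.1 and HOMER 4.10 were used, with no role given. Each stage has 1 peak list, so peaks have no replicate spread, and how libraries were combined, the peak caller, genome build and annotation release are not given in the sources used here.

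The expression values are FPKM per gene and input library as the authors deposited them, with Ensembl gene identifiers and symbols. Enrichments in the peak lists are log2 values of immunoprecipitate over input, 1 per peak and stage, per the file headers. P-values and adjusted p-values of peaks were used as deposited by the authors, and the largest p-value in the lists was 0.049. The deposited log2 change of differential peaks is MII against GV, and over 4255 peaks overlapping both lists the value in the authors' deposited table had a Spearman correlation of 0.80 with the MII minus GV enrichment. Values of single immunoprecipitated libraries were not analysed here. Peak starts count from 0 in the files, since 861 GV peaks start at the gene start minus 1 and 0 at the gene start, and they are printed counting from 1.

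Depth was read from the low values of short single-transcript RNAs, whose FPKM times length should be whole multiples of 1 base of coverage under StringTie's definition. Between 59.4% and 69.5% of 95 to 137 values per library lay within 0.05 steps of a whole number at the best of 60001 steps tried, against a median of 9.35% to 9.49% over those steps. That median is not what the best of many steps would reach without a signal, which was not estimated. Steps were searched only from 0.2 to 0.6 FPKM times base pairs, so multiples outside that range were not examined. The steps do not give whole reads, so no count test was run, and a stated depth is an estimate.

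Input expression was tested with limma 3.58.1 in R 4.3.3 (trended eBayes, 2-sided) on log2(FPKM + 1) for genes with a mean of at least 1 FPKM over the 6 input libraries, with Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. On data simulated for this comparison, with 200 of 11739 genes changed, 34.0% of changes of 0.5, 79.5% of changes of 1 and 99.0% of changes of 2 on the log2 scale were recovered. The data had 7140 calls, and the adjusted threshold is stricter with fewer changed genes, so these shares may understate recovery in the data. The 12 gene lists were fixed before the data were examined and tested with camera at a correlation of 0.01, with an estimated correlation beside it. List symbols were matched to the file's own symbols (385 matched, 45 not). A match through synonyms in the RefSeq table of assembly ARS-UCD2.0 was tried first and dropped after list results had been seen, because it returned other genes (RBMXL2, OOSP2 and EIF3CL). That changed no list's call.

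Genes were named by a rule fixed before the data were examined: adjusted p under 0.05, a mean of at least 5 FPKM, libraries of the stages not overlapping and a symbol, the 10 largest and 10 smallest changes, plus members of the lists. Peaks were named as the 10 highest by enrichment per stage and the 10 highest and 10 lowest differential peaks at an FDR under 0.05, in genes with a symbol and a mean of at least 1 FPKM, plus list members, and the text gives a part of them. Overlap needed 1 bp on the same strand. Shares of peaks have 95% Clopper-Pearson intervals. Expression and methylation were compared by permuting genes 100000 times within 10 strata of expression, in Python 3.11.15 with SciPy 1.17.1 and numba 0.67.0. The fit, the list test and this test were tested on simulated data.

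Alternatives were other pseudocounts, filters, scalings and variance models, each library left out, a replicate block, other overlaps, thresholds and strata. The m6A motif was not tested, because no genome sequence was used here. GC content was not examined for the same reason. A count-based test and the authors' own expression calls were not run.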

Results

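Bovine oocytes at the germinal vesicle (GV) stage, arrested in prophase of the first meiotic division, were compared with oocytes at metaphase of the second division (MII), the stage an oocyte reaches at the end of maturation. The oocytes were cultured in vitro, per the labels. The design asked how the N6-methyladenosine (m6A) map and the transcriptome differ between these stages. Each stage had 3 input libraries of poly(A) RNA and 3 libraries of RNA immunoprecipitated with an antibody against m6A, 12 libraries in all. Expression values were given for the 6 input libraries, while each stage had 1 list of m6A peaks and the stages shared 1 table of differential peaks. Nothing in the labels says that libraries of a stage came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

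Input libraries of a stage resembled each other more than those of the other stage. Spearman's correlation across genes was 0.988 between GV libraries, 0.974 to 0.976 between MII libraries and 0.923 to 0.927 across stages, and genes are not independent replicates. The step between low values of short RNAs implied 3.57, 3.53 and 3.56 gigabases of sequence, as an estimate, in GV libraries 1, 2 and 3, and 2.88, 3.44 and 4.61 gigabases in MII libraries 1, 2 and 3. Of 16675 genes, 3765, 3722 and 3733 were listed at 0 in the GV libraries, against 1485, 1282 and 1727 in the MII libraries. Genes used by every cell were among those at 0 in GV, so a 0 is given here only as a listed value.

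Transcripts of ribosomal proteins and respiratory chain subunits were higher in MII, as were OOEP, FIGLA and NPM2 among oocyte genes. The cyclin genes CCNB1 and CCNA2, the cohesin gene SMC3 and the exonuclease gene XRN1 were lower. Of 11739 genes tested, 7140 changed by limma with Benjamini-Hochberg adjustment, 3761 higher and 3379 lower in MII. A change of at least 1 on the log2(FPKM + 1) scale was reached by 1045 genes that rose and by 370 that fell. Without genes listed at 0 in every library of a stage these counts were 796 and 344, with 3495 higher and 3345 lower in all. Which direction had more calls depended on scaling and filter. There were 3823 higher and 3307 lower with median scaling, 3259 and 3995 after quantile normalization, and 2677 and 2687 with a filter at a mean of 5 FPKM. The majority turned too, to 3206 and 3928, when mitochondrial genes were removed and the rest rescaled. Tested genes at 0 in every GV library and above 0 in every MII library had a median genomic span of 5.64 kb. The other tested genes had 21.3 kb, and whether changes depended on transcript length was not tested.

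Of the 10 genes with the largest rise under the naming rule, 9 were listed at 0 in every GV library, so no fold is given for them. RPL36A (ENSBTAG00000019253), a ribosomal protein gene on chromosome X (50819017 to 50835992), was at 26.0, 29.1 and 26.4 FPKM in MII libraries 1, 2 and 3. MICOS13, a subunit of the mitochondrial contact site complex on chromosome 7, was at 22.9, 24.0 and 21.3 FPKM, and the transcription cofactor EYA2 on chromosome 13 at 21.9, 21.0 and 18.7 FPKM. LAMTOR5, of the lysosomal Ragulator complex, was at 15.8, 20.7 and 17.4 FPKM. SMIM26, AAMDC, LYRM7, LSM5 and bta-mir-11978 followed the same pattern. The remaining gene, bta-mir-187, was not listed at 0 throughout a stage and rose from 0.672 ± 0.503 to 26.8 ± 2.29 FPKM (SD, n = 3 each; limma adjusted p = 7.5e-06). Its GV mean was below 1 FPKM, so the size of its rise is uncertain. The libraries held fragmented poly(A) RNA, and whether values of bta-mir-187 and bta-mir-11978 come from mature microRNAs was not tested.

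The 10 genes with the largest fall were mostly small noncoding RNAs. A copy of U6, a spliceosomal small nuclear RNA (ENSBTAG00000043073, chromosome 22, 56018849 to 56018955), fell by 2.03 on the log2 scale, from 85.1 ± 16.7 to 19.9 ± 2.76 FPKM (SD, n = 3 each; limma adjusted p = 3.5e-05). A second U6 copy on chromosome 5 fell by 2.33 and a U1 copy on chromosome 18 fell by 2.75. U3 and SNORA55 were listed at 0 in every MII library, and U3 was at 14.6, 18.9 and 17.9 FPKM in GV libraries 1, 2 and 3. SNORA75, SCARNA10 and bta-mir-3064 were also in this group. The protein-coding members were SAMD5, which fell by 2.32, and SMIM10L1, which fell by 2.03. These RNAs have many near-identical copies and most lack a poly(A) tail, so their values are uncertain.

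Cytosolic ribosomal protein genes rose together. Of 79 tested members 69 rose and 1 fell (71 and 1 adjusted over the list alone), with a median log2 change of 0.90 (camera adjusted p = 4.9e-17; adjusted p = 0.0063 with an estimated correlation). RPLP1, a stalk protein of the large subunit, rose from 220.7 ± 8.36 to 825.6 ± 18.8 FPKM and RPL28 from 52.9 ± 4.55 to 215.0 ± 4.98 FPKM (SD, n = 3 each). RPL39 rose by 2.90 on the log2 scale (SE 0.17). Nuclear genes for respiratory chain subunits moved the same way, with 67 of 80 higher and 3 lower (69 and 3 adjusted over the list alone) and a median of 0.80 (camera adjusted p = 7.3e-12; adjusted p = 0.0063 with an estimated correlation). COX6A1 of cytochrome c oxidase rose from 15.1 ± 0.793 to 77.6 ± 6.55 FPKM, UQCRQ of complex III by 1.92 and ATP5F1E of the ATP synthase by 1.58 on the log2 scale. NDUFB1 of complex I rose by 2.83, and UQCR11 was listed at 0 in every GV library. Without genes listed at 0 throughout a stage, the medians were 0.89 and 0.78. FPKM is relative to the RNA of a whole library. The part of poly(A) tail length or transcript length in these rises was not tested.

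Messenger RNAs of the mitochondrial genome were higher in MII for 12 of 13 members and lower for 1, in both adjustments (adjusted over the list alone: 12 and 1). The median was 0.65 (camera adjusted p = 3.5e-05), but the call was lost with an estimated correlation (adjusted p = 0.20). ND5, a subunit of complex I, rose from 227.4 ± 3.17 to 633.9 ± 35.4 FPKM and COX1 from 689.1 ± 6.18 to 1303 ± 84.1 FPKM (SD, n = 3 each). ATP8 fell by 0.26 on the log2 scale (SE 0.067).

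Oocyte and maternal effect genes leaned towards MII, with 18 of 30 higher and 5 lower (19 and 5 adjusted over the list alone) and a median of 0.32 (camera adjusted p = 0.0090; adjusted p = 0.20 with an estimated correlation). OOEP, of the subcortical maternal complex, rose from 15.0 ± 0.435 to 48.2 ± 8.51 FPKM. FIGLA, an oocyte transcription factor, rose by 1.30, the chaperone NPM2 by 1.24, the zona pellucida gene ZP3 by 0.92 and the growth factor gene GDF9 by 0.63 on the log2 scale. OOSP2, an oocyte secreted protein, fell from 512.2 ± 7.04 to 246.3 ± 17.2 FPKM (SD, n = 3), and UHRF1, which maintains DNA methylation, fell by 0.45.

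Meiosis and cell cycle genes were lower in MII for 30 of 63 members and higher for 17 (31 and 17 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.034; adjusted p = 0.20 with an estimated correlation). CCNB1 (ENSBTAG00000014239), the cyclin partner of CDK1, fell by 0.94 on the log2 scale (SE 0.034), from a mean of 1471 to 768.6 FPKM. CCNA2 fell from 144.1 ± 6.50 to 69.9 ± 0.468 FPKM (SD, n = 3 each). FBXO43, an inhibitor of the anaphase-promoting complex, fell by 1.29 and the cohesin gene SMC3 by 0.95. The phosphatase gene CDC25B rose by 0.52, CDK2 by 0.62 and the checkpoint gene BUB3 by 0.66. MOS, the kinase upstream of MAPK in oocytes, had a log2 change of -0.043 (SE 0.049), called at -0.13 only without mitochondrial genes (adjusted p = 0.048; 0.048 to 0.99 over alternatives), and REC8 was listed at 0 in every GV library. The list's call was also lost after quantile normalization (adjusted p = 0.057; 0.0022 to 0.20 over the camera alternatives).

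Genes of mRNA decay and poly(A) control had 26 of 64 members lower and 13 higher (26 and 13 adjusted over the list alone), a median of -0.078 and no call for the list (camera adjusted p = 0.060; adjusted p = 0.20 with an estimated correlation). XRN1, the 5'-to-3' exonuclease, fell by 0.97, CPEB2 by 1.29, the deadenylase genes PAN3 and CNOT6L by 0.80 and 0.61. BTG4, an adaptor of the deadenylase complex, fell from 1945 ± 26.7 to 1605 ± 69.1 FPKM (SD, n = 3 each). The call was lost with quantile normalization, where its log2 change was -2.3e-15. A gene of the same rank in every library gets no change there by construction, so that alternative cannot test the call. CPEB3 rose from 4.74 ± 0.827 to 15.2 ± 0.359 FPKM and the cap-binding EIF4E1B from 396.0 ± 15.5 to 795.6 ± 28.9 FPKM (SD, n = 3 each), the poly(A)-binding PABPC1L by 0.70 and the RNA storage protein gene YBX2 by 0.58. The list passed when GV library 1 was left out (adjusted p = 0.048; 0.0094 to 0.20 over the camera alternatives).

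The m6A machinery was lower in MII for 12 of 26 members and higher for 3, in both adjustments (adjusted over the list alone: 12 and 3). The median was -0.21 and the list did not pass (camera adjusted p = 0.0504; adjusted p = 0.20 with an estimated correlation). Among writers, METTL3 (ENSBTAG00000015148, chromosome 10, 25661794 to 25677142), the catalytic subunit, fell from 4.52 ± 0.751 to 2.87 ± 0.518 FPKM (limma adjusted p = 0.021) and its adaptor WTAP (ENSBTAG00000007974) from 58.0 ± 0.718 to 34.4 ± 2.69 FPKM (adjusted p = 5.4e-05; SD, n = 3 each). VIRMA fell by 0.30, whereas METTL14, the partner of METTL3, rose from 27.8 ± 0.564 to 39.2 ± 1.45 FPKM (limma adjusted p = 0.00015). The erasers moved apart, as FTO fell by 0.54 and ALKBH5 rose by 0.36. Among readers, ELAVL1 fell by 0.71, FXR1 by 0.46, FMR1 by 0.45 and YTHDF2 by 0.37, while FXR2 rose by 0.37. YTHDF3 and YTHDC1 had log2 changes of -0.11 and 0.097, with adjusted p of 0.30 and 0.29 in limma. The METTL3 call ended without GV library 2 (adjusted p = 0.073; 0.0074 to 0.073 over alternatives) or MII library 1 (0.065), and that of YTHDF2 without GV library 1 (0.051), GV library 2 (0.056) or MII library 3 (0.0504; 0.0051 to 0.056 over alternatives). The list passed without GV library 1 (adjusted p = 0.040), GV library 3 (0.049) or MII library 3 (0.049), with a range of 0.012 to 0.20 over the camera alternatives.

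**Figure D1:**
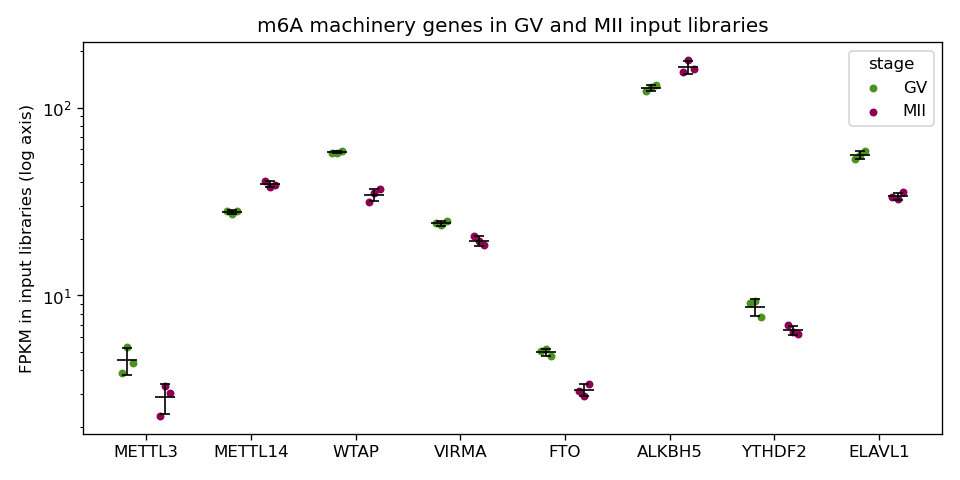
FPKM on a log axis of 8 m6A machinery genes in the 3 GV and 3 MII input libraries, with points for libraries and bars for mean and SD. METTL14 and ALKBH5 lie higher in MII and the other genes lower.

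Chromatin genes split, with 21 of 58 lower and 11 higher (20 and 9 adjusted over the list alone), a median of -0.059 and no call for the list (camera adjusted p = 0.11; adjusted p = 0.20 with an estimated correlation). HDAC3, a histone deacetylase, fell by 0.82 and the remodeller SMARCA5 by 0.76, while the methyltransferase KMT5A rose by 0.80. Translation factors had 15 of 48 higher and 14 lower in both adjustments (adjusted over the list alone: 15 and 14), with a median of -0.016 against a mean of 0.087, on the side the test took (camera adjusted p = 0.99; adjusted p = 0.99 with an estimated correlation). EIF1AX rose by 1.38 and EIF3H by 1.21, while EIF4A2 fell by 0.96 and EIF3L by 0.81. Redox and stress genes had 17 of 34 higher and 6 lower in both adjustments (adjusted over the list alone: 17 and 6), a median of 0.26 and no call (camera adjusted p = 0.0504; adjusted p = 0.20 with an estimated correlation). The chaperonin gene HSPE1 rose by 1.38, the peroxiredoxin PRDX1 by 0.95 and XBP1 by 0.76, and catalase, CAT, fell by 0.57. The redox list passed without GV library 1 (adjusted p = 0.039), GV library 3 (0.049) or MII library 3 (0.049), with a range of 0.032 to 0.20 over the camera alternatives.

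Of the markers of cumulus and granulosa cells, 29 were above 0 in at least 1 input library, and only 15 had a mean of at least 1 FPKM. Of those 15, 8 were lower and 4 higher in MII in both adjustments (adjusted over the list alone: 8 and 4). Their median was -0.29 (camera adjusted p = 0.14; adjusted p = 0.20 with an estimated correlation). VIM fell from 6.31 ± 0.846 to 0.429 ± 0.513 FPKM, PTGS2 from 15.3 ± 0.621 to 5.98 ± 1.18 FPKM and HAS2 by 0.65 on the log2 scale (SD, n = 3 each). CLU rose from 2.25 ± 0.143 to 6.47 ± 1.11 FPKM and GREM1 by 0.97. STAR was at 149.1 ± 7.20 FPKM in GV and 167.2 ± 2.32 in MII, a call lost without mitochondrial genes (adjusted p = 0.20; 0.0077 to 0.20 over alternatives) and in eBayes without trend (0.060). Of the theca, blood and immune markers 3 were tested and 2 rose (2 adjusted over the list alone), HBA by 1.28 and VWF by 0.44, and CSF1R had a log2 change of 0.097 (camera adjusted p = 0.18; adjusted p = 0.26 with an estimated correlation).

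**Figure D2:**
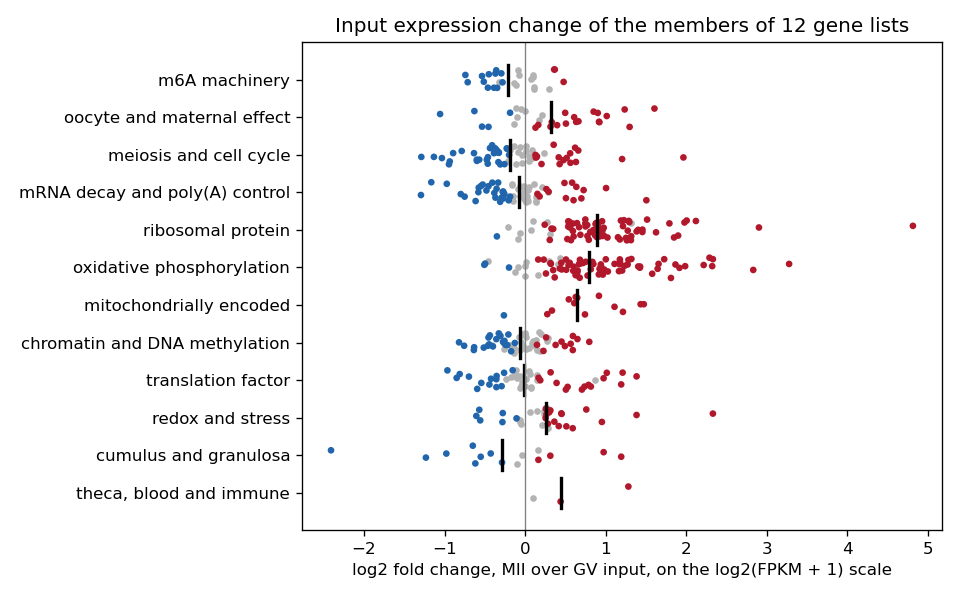
Log2 fold change of MII over GV input (log2(FPKM + 1) scale) for the tested members of 12 gene lists, 1 point per gene, red or blue where limma's adjusted p was under 0.05 and grey otherwise, with a black bar at the median. Ribosomal protein and oxidative phosphorylation genes lie to the right, with medians of 0.90 and 0.80, and values of genes listed at 0 in GV, such as RPL36A, depend on the pseudocount.

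The m6A map of GV oocytes held 14222 peaks in 6705 genes and that of MII oocytes 22298 peaks in 9655 genes. Each stage has 1 list, with no replicates, and enrichments are the authors' values for the peak. The median log2 enrichment over input was 2.62 in the GV list and 1.67 in the MII list. At an FDR under 0.05 there were 10791 GV peaks and 18416 MII peaks. Depth and efficiency of the immunoprecipitated libraries were not examined, so these values do not measure a difference in methylation between the stages. The highest GV enrichment was in ZNF184, a zinc finger gene, with a log2 value of 8.11 in a peak over the stop codon (chromosome 23, 31174761 to 31184529). Exonic GV peaks of the histone chaperone gene DAXX (chromosome 23, 7488818 to 7489441) and of ZEB1 (chromosome 13, 33773152 to 33773571) had 7.64 and 7.44. In MII the highest was 5.67 in the 5' UTR of HNRNPH3, an RNA-binding protein gene (chromosome 28, 24751676 to 24752194). YTHDF3, itself an m6A reader, had a MII peak with 5.35 in its 5' UTR (chromosome 14, 28141155 to 28145049). Coordinates are those of the authors' files, whose genome build is not given in the sources used here, and spans include introns.

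MII peaks lay more often on the plus strand. Of the MII peaks 12875 were on the plus and 9423 on the minus strand, against 7242 and 6980 in GV. Among tested protein-coding genes, 82.7% of 5583 on the plus strand and 73.3% of 5365 on the minus strand carried a MII peak, against 57.5% and 57.1% with a GV peak. Median input log2 change was 0.02 on either strand.

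**Figure D3:**
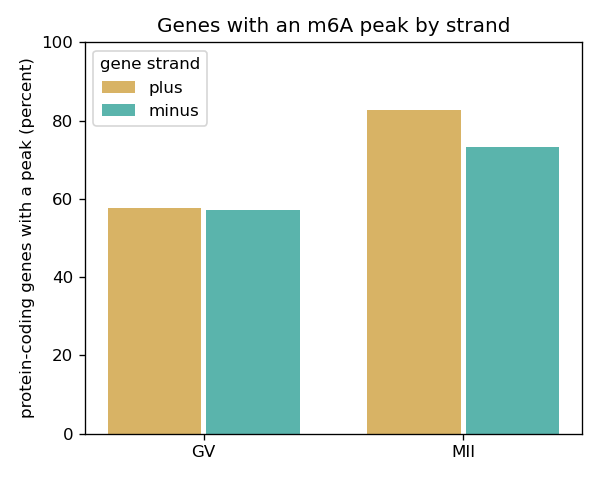
Percent of tested protein-coding genes with an m6A peak, by stage and gene strand. The bars are at 57.5% and 57.1% in GV and at 82.7% and 73.3% in MII, for the plus and minus strand.

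Overlap of the peak lists depended on their length and on the rule. By at least 1 bp on the same strand, 64.1% of GV peaks overlapped a MII peak and 39.9% of MII peaks overlapped a GV peak. Of the 11739 tested genes, 6351 had a GV peak, 8669 a MII peak and 5763 both, where independent lists would share 4690. Peaks in MII but not GV were found in 2906 genes and the reverse in 588, with a longer MII list. With the same number of peaks from each list 49.2% of GV and 44.5% of MII peaks overlapped, and 2099 genes had peaks in MII but not GV and 1370 the reverse. Above the median enrichment the shares were 44.3% and 28.6% and the genes 2944 and 1144. With a reciprocal overlap of 50% of each peak's span, the shares were 27.8% and 17.7%.

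Peaks at the start of the transcript took a larger part of the MII list and those at the stop codon a smaller part. Start codon peaks made up 5.90% of the GV list (95% exact interval 5.52% to 6.30%) and 10.5% of the MII list (10.1% to 10.9%). The 5' UTR had 4.33% (4.00% to 4.68%) and 6.27% (5.96% to 6.60%). The stop codon had 9.30% (8.82% to 9.78%) and 6.18% (5.86% to 6.50%), and the intervals for the 3' UTR overlapped (13.5% to 14.6% and 13.9% to 14.9%). Among peaks spanning at most 250 bp, start codon peaks made up 2.81% and 4.49% and stop codon peaks 6.26% and 4.31%. The summed stop codon and 3' UTR share turned direction there, with 34.4% in GV and 36.2% in MII, and was level on the plus strand at 21.6% in each. Exonic peaks were the majority in both, 65.6% and 61.6%. These intervals cover counting error only, since the lists have no replicates.

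**Figure D4:**
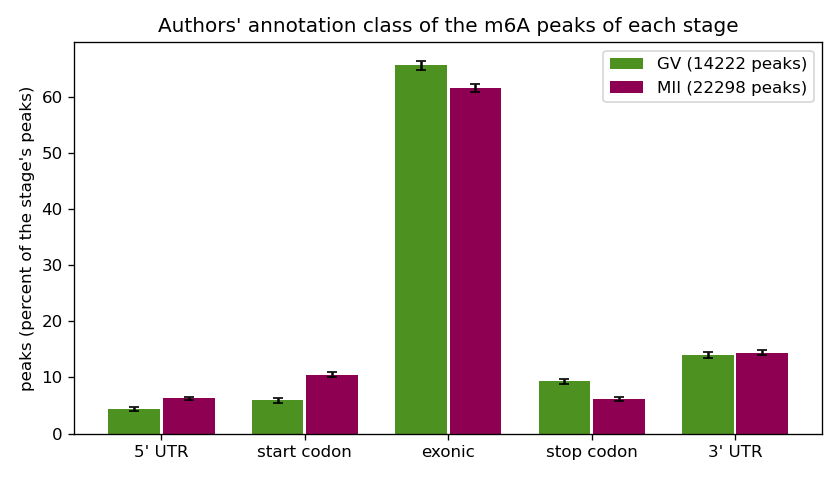
Percent of the peaks of each stage in 5 annotation classes given by the authors, with 95% exact binomial intervals as bars. Start codon peaks rise from 5.90% in GV to 10.5% in MII and stop codon peaks go from 9.30% to 6.18%.

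The authors' deposited table of differential peaks held 8682 peaks, and at an FDR under 0.05 it had 5468 peaks higher and 2689 lower in MII. In the authors' deposited table, 2906 genes had only higher peaks, 1179 only lower peaks and 726 both. Higher peaks in the authors' deposited table overlapped a MII peak alone in 65.2% of cases and a peak of both stages in 34.7%, while 77.0% of lower peaks overlapped both. By strand, the authors' deposited table had 3282 higher and 1111 lower peaks on the plus strand, and 2186 higher and 1578 lower on the minus strand. In the authors' deposited table, start codons held 17.0% and stop codons 5.41% of the higher peaks, against 7.74% and 13.8% of the lower peaks.

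The largest rise in the authors' deposited table was in PCNP, a nuclear protein gene, with a log2 change of 7.16 over the stop codon (chromosome 1, 46010077 to 46015163). MCM7, a subunit of the replicative helicase, had 6.12 in its 5' UTR (chromosome 25, 36349499 to 36349894) and SDHB of respiratory complex II had 6.05 (chromosome 2, 135548937 to 135554397) in the authors' deposited table. The largest fall in the authors' deposited table was in an exon of ZBTB21, a zinc finger gene (chromosome 1, 142239981 to 142240101), at -7.03. A second exonic peak of ZEB1 (chromosome 13, 33774025 to 33776138) was at -5.53 in the authors' deposited table. Among oocyte genes, TRIM28 had 4.75 (chromosome 18, 65773872 to 65773932) and LHX8 3.88 (chromosome 3, 69652610 to 69653295), and GDF9 had -1.05 over its stop codon (chromosome 7, 44442696 to 44443650) in the authors' deposited table. Of m6A machinery genes, ALKBH5 had an exonic peak at 1.70 and YTHDF1 one at -2.24 in the authors' deposited table. By list, the authors' deposited table gave only higher peaks to 20 ribosomal protein genes and 28 oxidative phosphorylation genes and only lower peaks to 1 of each. Over all genes, the authors' deposited table had 2906 with only higher and 1179 with only lower peaks. A GV peak was present in 16 of 79 and 17 of 80 tested genes of these lists, and a MII peak in 42 and 49. Whether these lists differed from all genes was not tested. For the m6A machinery list the authors' deposited table gave only higher peaks to 7 genes, only lower peaks to 6 and both to 6.

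Whether methylation and abundance changed together was asked across genes, and the answer moved with how expression was held constant. Genes with only higher peaks in the authors' deposited table (2891 tested) had a mean input log2 change of 0.015 and genes with only lower peaks (1172) of 0.025. Within deciles of mean input expression the difference beyond that expected was 0.013 (two-sided permutation test across genes, 100000 resamples, p = 0.47). With deciles of GV expression instead it was 0.062 (permutation p = 0.00042). Neither set passed camera (adjusted p = 0.32 for both; adjusted p = 0.42 for both with an estimated correlation).

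Genes with a GV peak had a lower mean change than genes without one, 0.047 in 6351 genes against 0.16 in 5388. Within deciles of mean expression the difference beyond that expected was -0.079 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give), and -0.13 with a filter at a mean of 5 FPKM (permutation p = 1e-05). Within deciles of GV expression the difference was 0.0054 (permutation p = 0.64), so the result rests on how expression is held constant. Both relations are across genes, which are not independent replicates, and peaks and expression share the input libraries.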

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

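All tests of explanations in this part were chosen after the result was seen. The enrichment over input differed between the stages for 8157 peaks at an FDR under 0.05 in the authors' deposited table, a difference between groups under the same contrast, tested by the authors.

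MII peaks, and peaks higher in MII, lay in excess on the plus strand, and the libraries were made to keep the strand. Within deciles of expression, plus-strand genes carried a MII peak more often by 9.60 percentage points (95% interval 8.14 to 11.1), which argues against expression level as the whole cause. In genes overlapping no other gene the difference was 9.24 points, which argues against reads from overlapping genes, and 30 of 30 chromosomes with at least 100 MII peaks had a plus share above that of their tested genes. The authors' log2 change had a median higher by 0.61 on the plus strand in the authors' deposited table. Median input log2 change was 0.02 on either strand. A difference in how strands were handled in the MII immunoprecipitates or the calling may remain. It could not be tested, because single immunoprecipitated libraries were not analysed here. The strand of a gene is only its orientation in the assembly, and the excess held on 30 of 30 chromosomes. This argues against the stage as a biological explanation of the excess. Counts of higher and lower peaks carry this limit.

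Of genes with a mean of at least 1 FPKM, 246 were listed at 0 in every GV library and above 0 in every MII library, against 25 the other way. MII library 1 had an implied 2.88 gigabases, below all GV libraries, and fewer genes at 0. This argues against lower GV depth only if all steps are the same multiple of 1 base, which was not examined. Of the 246 genes, 40 overlap no other gene yet carry a GV peak, 21 of them at an FDR under 0.05. This argues against absence of the RNA for those 21. Reads shared with similar genes elsewhere were not examined. At a MII mean of 2 to 8 FPKM a GV peak was less frequent in genes at 0 in GV than in other genes, 20.8% of 221 against 47.8% of 3467, or 40.9% with the other genes weighted to the same, shorter genomic spans (2-sided permutation across genes within deciles of span, p = 1.0e-04, the smallest that 10000 resamples can give), so absence or a lower level stays open for the rest. Of genes at 0 in any GV library 81.1% were at 0 in all 3, against 12.2% in MII. Zeros set for the GV libraries together may therefore contribute. Real absence in this stage would give this too, and these cannot be told apart for the remaining genes. The 246 genes had a median genomic span of 5.64 kb, against 21.3 kb in the other tested genes. The part of transcript length in these zeros was not tested.

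The start codon share of peaks was larger in MII by 4.58 points, 6.33 on the minus strand and 3.05 on the plus strand. With the same number of peaks from each list the difference was 6.63 points, and in genes with peaks in both stages 3.80 points, which argues against weaker extra peaks and against genes with peaks in 1 stage as the whole cause. Among peaks spanning at most 250 bp it was 1.68 points (95% interval 1.08 to 2.27), from 2.81% in GV and 4.49% in MII. Both shares were lower there than over all peaks, and spans include introns. This limit therefore cannot decide whether wider peaks account for part of the difference, which cannot be told apart from a change in position. The stage itself remains open as an untested biological explanation.

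For the count of 7140 changed genes, 1 of the 10 splits of the 6 input libraries, the real one, gave as many, and the highest other split gave 1 gene. With 10 splits no share under 0.05 can be reached.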

How the results depend on the processing

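The strand, span, stop codon, zero-gene and protein-coding alternatives, and the lists under a pseudocount of 0.5, a filter of 5 FPKM, removal of mitochondrial genes and other variance models, were chosen after seeing the data. Of 1714 values of 92 named genes under alternatives, 1705 kept their side of the threshold, 8 lost the call (METTL3, YTHDF2, STAR and BTG4), 1 gained it (MOS) and no called value changed direction. Of 446 values of 31 other results, 371 were labelled the same, 5 weaker, 26 stronger, 43 moved and 1 reversed. Counts and shares have no threshold, so for them the same means only a size close to the value given above. It does not mean that a majority kept its direction. The counts of 3259 higher and 3995 lower genes after quantile normalization were labelled the same, against 3761 and 3379. Where a value below moved, the cause was not tested unless fewer peaks or genes entered by construction.

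The count of changed genes stayed between 6339 and 6500 when each library was left out. Those higher were 3405 to 3471 and those lower 2905 to 3065. For changes of at least 1 the ranges were 1033 to 1073 and 364 to 394. With a filter at a mean of 5 FPKM, genes higher by at least 1 went from 1045 to 505 and lower from 370 to 173, and a pseudocount of 0.1 FPKM gave 579 lower. Fewer genes enter with the filter.

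Replicate numbers did not pair the libraries, as same-numbered deviations correlated at -0.055, -0.060 and 0.013, and only number 3 correlated best with its own. With a replicate block 6813 genes changed, 3612 higher and 3201 lower, and among the lists only redox changed its call (median 0.26, adjusted p = 0.044).

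With an estimated correlation the oocyte (median 0.32), meiosis (-0.19) and mitochondrially encoded (0.65) lists lost their call. The meiosis list also lost it with a filter of 5 FPKM (-0.17) and quantile normalization (-0.23). fry, which does not compare a list with other genes, called the m6A machinery (-0.21), mRNA decay (-0.078), chromatin (-0.059), translation (upwards, by a mean of 0.087 beside a median of -0.016), redox (0.26), cumulus (-0.29) and theca (0.44) lists. With no filter the m6A machinery (-0.13), mRNA decay (-0.066) and chromatin (-0.043) lists passed. Without mitochondrial genes the m6A machinery (-0.29) and mRNA decay (-0.16) lists passed, and the mitochondrially encoded list has no value. A pseudocount of 0.5 and arrayWeights passed the m6A machinery (-0.21 in each) and redox lists (0.26 in each), and so did removal of genes at 0 for the redox list (0.26). Leaving out each library gave medians of -0.24 to -0.19 for the m6A machinery, 0.30 to 0.34 for oocyte, -0.20 to -0.13 for meiosis, -0.10 to -0.070 for mRNA decay, 0.88 to 0.90 for ribosomal, 0.75 to 0.84 for oxidative phosphorylation, 0.62 to 0.67 for mitochondrially encoded, -0.081 to -0.054 for chromatin, -0.037 to -0.0099 for translation, 0.25 to 0.27 for redox, -0.35 to -0.25 for cumulus and 0.42 to 0.48 for theca genes.

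Above the median enrichment there were 7108 GV and 11131 MII peaks by construction, 3101 genes with peaks in both stages, and overlaps of 44.3% and 28.6%. Overlaps were 57.5% and 35.7% with 50% of the shorter peak, 27.8% and 17.7% with a reciprocal overlap, 49.2% and 44.5% with the same number of peaks and 69.3% and 45.1% in genes at 5 FPKM in each stage. The share at the start codon and 5' UTR in GV was 10.9% at a stricter FDR, 12.1% on the plus and 8.28% on the minus strand. In MII it was 19.2% above the median enrichment, 18.2% at a stricter FDR, 18.1% in genes at 5 FPKM, 16.2% and 17.6% on the plus and minus strand and 14.7% for short spans. The share at the stop codon and 3' UTR in GV was 26.6% above the median enrichment, 20.6% at a stricter FDR, 21.6% and 25.1% on the plus and minus strand and 34.4% for short spans. In MII it was 22.0%, 18.7%, 21.6%, 19.2% and 36.2% in the same order, so this share, lower in MII over all peaks, was higher in MII for short spans and level on the plus strand. The stop codon alone was lower in MII for short spans (6.26% and 4.31%) and on the plus strand (8.74% and 6.71%). In the authors' deposited table, the plus strand had 3282 higher and 1111 lower peaks (74.7% higher) and the minus strand 2186 and 1578 (58.1%). The percent higher in the authors' deposited table was 68.3% at an FDR under 0.01 and 70.2% at an absolute log2 change of at least 1.

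With strata of GV expression the difference by methylation change passed at 0.062 and that of GV-methylated genes turned to 0.0054, and leaving out each library gave 0.0084 to 0.018 and -0.086 to -0.073. With a filter at a mean of 5 FPKM they were 0.027 and -0.13, and with no strata -0.010 and -0.12. The motif alternatives, the authors' expression calls and a count test were not run. A change of 0.5 was recovered for 34.0% of simulated genes, with 200 of 11739 genes changed against 7140 called in the data. The adjusted threshold is stricter with fewer changed genes, so this share may understate recovery in the data. The part that depth has in recovery was not tested.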

Other observations

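The analyses of gene ontology terms in this part were chosen after the data were seen. Beyond the fixed lists, 20 of 1265 terms were higher and 11 lower in MII by camera, and 0 of either with an estimated correlation in camera, where 41 had an unadjusted p under 0.05 and the smallest adjusted p was 0.96. Genes of the term structural constituent of chromatin, which covers histones, had 54 of 78 members lower and 7 higher, with a median of -0.66 (camera adjusted p = 1.6e-07; adjusted p = 0.96 with an estimated correlation). The beads selected poly(A) RNA, so lower values of these genes cannot be told apart from a change in tails. For the term pre-mRNA 5'-splice site binding 25 of 35 members were lower, with a median of -0.73, and for mitochondrial respiratory chain complex IV 15 of 16 were higher, with a median of 1.08 (camera adjusted p = 2.3e-05 for both; adjusted p = 0.96 for both with an estimated correlation).

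Genes whose peaks only rose and genes whose peaks only fell in the authors' deposited table differed in some terms. Expression, transcript length and strand were not held constant in this comparison, so their part in it is open. Of 452 terms, 16 differed by 2-sided Fisher's exact test with Benjamini-Hochberg adjustment, and 64 at an unadjusted p under 0.05. Regulation of DNA-templated transcription had 92 genes with only higher and 94 with only lower peaks in the authors' deposited table, 49.5% higher against 71.2% over all such genes (adjusted p = 1.0e-07). Terms that leaned the other way included mitochondrion, with 192 and 46 genes, and endosome, with 39 and 3 genes, in the authors' deposited table.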
